A study of Mus musculus with 9 samples.

How the data were processed

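RNA was measured in 9 libraries from the initial segment of the mouse epididymis at 4 weeks of age. The labels give the strain as C57BL/6, total RNA treated with DNase I, selection of mRNA with oligo(dT) and standard Illumina libraries. The groups were wild type (WT), a double knockout of Mst1 and Mst2 (dKO) and a triple knockout of Mst1, Mst2 and Yap (tKO), with 3 libraries in each. Mst1 is Stk4, Mst2 is Stk3 and Yap is Yap1. Nothing in the labels says that the libraries came from separate animals, so every p-value measures the spread between these samples.

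The deposited values are FPKM, 1 file per library, per the file headers. Each value belongs to 1 transcript event: a first exon, a last exon, a skipped or included exon, a retained intron or an alternative exon. Events at 0 are not listed. The files held 133642 distinct events in 18650 loci. The authors' processing notes name bcl2fastq 2.17.1.14 and DESeq, without saying which step used them. The aligner and the genome build are not given in the sources used here. The files hold no read counts, so the sequencing depth behind each value is unknown, and no counting interval or detection limit could be given.

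Event positions were compared with GENCODE release M21 of the mouse genome build GRCm38. Of 36623 first-exon events 81.5% ended at an annotated splice site, as did 82.4% of 21612 last-exon events. Events that ended at none were placed in the gene the files name if they lay within 5000 bases of it. In the library with the lowest share, 94.7% of the first-exon FPKM and 96.8% of the last-exon FPKM could be placed in a gene. The value of a gene was the sum of its first-exon events or of its last-exon events, whichever class was larger in total over the 9 libraries. This gave a value to 16954 genes, 12471 of them by first exons and 4483 by last exons, and to 14843 of the 21951 annotated protein-coding genes. The sum is a lower bound: of 11235 tested genes alone in their locus, 58 had a single event above 1.5 times the gene value. Reads of paralogs could not be separated.

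Genes with at least 1 FPKM in at least 3 libraries were tested, 12021 in all. limma 3.58.1 in R 4.3.3 fitted log2(FPKM + 1) with a mean-variance trend in 1 model of the 9 libraries, with 6 residual and 2.89 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all tested genes in each comparison, and a gene was called changed at an adjusted p under 0.05. The pseudocount of 1 makes log2 fold changes smaller than the ratios of means for genes at low levels. The self-test added known changes to simulated data with the observed spread. It recovered 66 to 71 of 100 changes of size 1 and 95 to 100 of 100 changes of size 2 on the log2 scale, none in the wrong direction, and called 6 to 9 unchanged genes in each comparison.

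Of 35 gene lists, 25 had at least 5 tested members and were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over the 25 lists. The same lists were tested with a correlation estimated from the data and with fry. Within each list, p-values were also adjusted over the list alone. The lists covered the Hippo pathway, other signalling pathways, genes of the initial segment and of later segments, cell type markers and gene families. The lists of lymphocyte, neutrophil and mitochondrial genes had no tested member. In simulated data with the cell cycle list shifted by 0.5, camera called that list and 1 other of the 25. The simulated genes were independent, while the correlation estimated for the cell cycle list was 0.53. The simulation thus does not test camera on correlated genes. Principal components used the 1000 tested genes with the largest variance.

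Genes are named by a rule. It takes the targeted genes Stk4, Stk3 and Yap1, and the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 FPKM in the higher group. All 3 libraries of one group had to lie above all 3 of the other, and predicted gene models (symbols starting with Gm or ending in Rik) were left out. Up to 4 members of each list with the smallest adjusted p could be named, and any tested member of the Hippo and initial segment lists. A gene named in one comparison is also followed into the others.

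Skipped exons of Stk4 and Stk3 were read from the event values, and group differences were tested with exact permutations of the 6 libraries, two-sided. Inclusion shares of other exons and of retained introns were tested with limma on percentages. For the changes of dKO in tKO, 100 simulated draws gave the values to compare with, with groups that do not differ from WT, with tKO equal to dKO, and with the changes of dKO in dKO only. Changes were given only to the 457 genes called in dKO versus WT, and noise was drawn independently for each gene. The ranges can thus be narrower than between real libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for reading, exact tests and figures.

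The comparisons, the test, the threshold, the lists, the rule for naming genes and the alternatives were set before the data were examined, except the following. The definition of a gene's value, the exon pairs of Stk4 and Stk3, the tests of inclusion shares and the alternatives of median-of-ratios scaling, first exons only, last exons only, the larger sum in each library and lists without Yap1 were, like a pseudocount of 0.1 and only the 6 libraries for the targeted genes, chosen after the data had been seen. The other alternatives were quantile normalization, a pseudocount of 0.1, no filter on low values, only the 6 libraries of the groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, and leaving out each library in turn. Tests that need read counts were planned as alternatives and could not be run on FPKM. Alternative exon events were not used here, and retained introns only for inclusion shares.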

Results

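Poly(A)-selected RNA was measured in the initial segment of the epididymis, the most proximal part of the duct, in 3 WT, 3 dKO and 3 tKO libraries. The files list FPKM, so sequencing depth is unknown. First-exon FPKM totalled 231670 to 253235 per library, and 13518 to 15114 genes were above 0. Gpx5, which encodes a secreted glutathione peroxidase of the epididymis, was the highest gene in every library, at 10682 to 17615 FPKM or 4.35% to 6.70% of the sum of all gene values, which was 244125 to 262960. Pearson's r across genes, which are not independent replicates, was 0.940 to 0.959 between libraries of a group and 0.906 to 0.952 between groups. The first principal component held 29.0% of the variance. It placed dKO at -21.7 to -10.3, WT at -7.33 to -0.10 and tKO at 8.01 to 30.8, with tKO replicate 2 at its end. The second held 20.8% and placed WT at 14.8 to 19.1, dKO at -13.6 to -11.1 and tKO at -11.6 to 0.39. Libraries with the same number were no more alike than others, so replicate numbers were not treated as pairs. Values are means ± SD over 3 libraries, and positions are on GRCm38.

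The targeted genes were examined first. Stk4 (ENSMUSG00000018209, chromosome 2, 164070322 to 164155524) encodes the kinase Mst1. Transcripts lacking its exons 4 and 5 of 11, at 164086495 to 164086609 and 164088841 to 164089005, made up 0% in each WT library, 64.3% ± 4.64 in dKO and 47.1% ± 19.6 in tKO. By library, the share was 68.6%, 64.8% and 59.4% in dKO and 58.7%, 58.0% and 24.5% in tKO; without tKO replicate 3 the tKO mean was 58.4%. The form that keeps both exons had 9.69 ± 0.84 FPKM in WT, 2.99 ± 0.17 in dKO and 4.76 ± 2.24 in tKO, where replicate 3 had 7.35. Stk3 (ENSMUSG00000022329, chromosome 15, 34875496 to 35178921) encodes Mst2. Transcripts lacking its exons 5 and 6 of 11, at 35073057 to 35073221 and 35072430 to 35072597, made up 0% in WT, 56.4% ± 6.84 in dKO and 39.9% ± 2.81 in tKO. The form that keeps them had 7.85 ± 0.93 FPKM in WT, 3.28 ± 0.87 in dKO and 4.13 ± 0.08 in tKO. Exact permutation tests of both shares gave a two-sided p of 0.1 in every comparison of groups, the smallest that 3 against 3 libraries allow. These exon pairs were chosen after their values were seen.

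Total Stk4 and Stk3 were not called changed, with a log2 fold change in dKO versus WT of -0.18 for Stk4 (limma, Benjamini-Hochberg adjusted p 0.50) and -0.07 for Stk3 (0.83). Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596), the transcriptional coactivator held back by the Mst kinases, had 25.1 ± 1.84 FPKM in WT, 26.5 ± 1.35 in dKO and 8.62 ± 0.27 in tKO. It fell by 1.44 on the log2 scale in tKO versus WT (limma, adjusted p 3.1e-04) and by 1.51 in tKO versus dKO (3.0e-04), and was not called in dKO versus WT (0.08, 0.72). The Yap1 values sum its first exons. In tKO the main first exon had 8.76, 5.65 and 8.20 FPKM, and another added 3.03 in replicate 2.

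**Figure D1:**
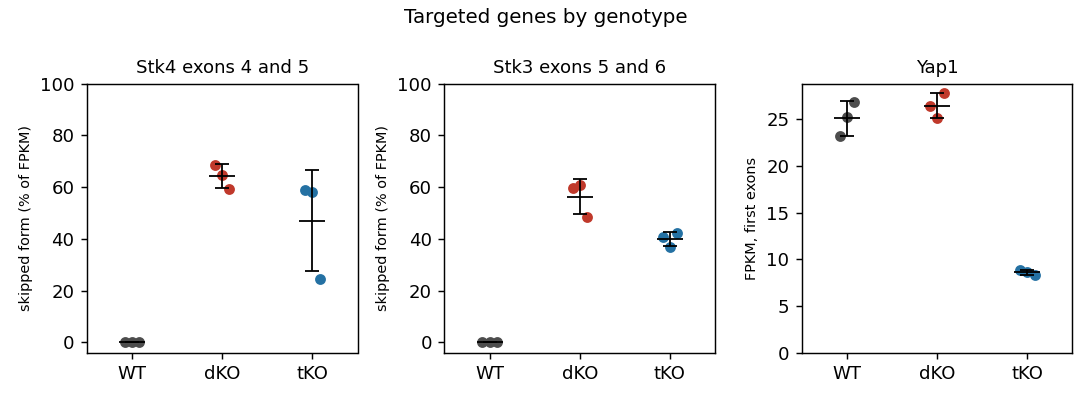
Share of transcripts skipping exons 4 and 5 of Stk4 and exons 5 and 6 of Stk3 (percent of FPKM), and FPKM of Yap1, in the 9 libraries (points) with the mean and SD of each group. Skipped forms are at 0% in WT, and Yap1 is at 8.62 FPKM on average in tKO against 25.1 in WT.

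The comparison of dKO with WT asks which transcripts of the initial segment depend on Mst1 and Mst2. Several genes for secreted proteins fell, among them the lipocalin Lcn8, the cystatins Cst8 and Cst12 and the ribonuclease-like Rnase10. Etv4 and Etv5, transcription factors that respond to ERK signalling, fell with them. Crisp1, Igfbp2 and the Hippo regulators Amot and Amotl2 rose. Of 12021 tested genes 457 were called changed, 176 higher and 281 lower, and 185 of them changed by at least 1 on the log2 scale, 52 up and 133 down. At an unadjusted p under 0.05 there were 2226. In all 457 the 3 libraries of one group lay above the 3 of the other, which held for 27.6% of all tested genes where chance gives 10%. The count was 106 without WT replicate 2, 127 without WT replicate 3, and 188, 164 and 135 without dKO replicates 1, 2 and 3. The balance of directions moved with it: there were 20 higher and 115 lower without dKO replicate 3, but 180 and 194 without WT replicate 1.

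Lypd8 (ENSMUSG00000013643, chromosome 11, 58379043 to 58390728) fell from 746 ± 207 to 76.9 ± 19.8 FPKM, a log2 fold change of -3.26 (limma, Benjamini-Hochberg adjusted p 0.0041). Cst8 (ENSMUSG00000027442, chromosome 2, 148798785 to 148805595) fell from 512 ± 162 to 68.3 ± 30.8 FPKM (-2.93, limma adjusted p 0.0044). Its neighbour Cst12 (ENSMUSG00000027443, chromosome 2, 148789361 to 148793546) fell from 123 ± 12.8 to 16.2 ± 2.52 FPKM (-2.85, limma adjusted p 8.5e-04). Lcn8 (ENSMUSG00000036449, chromosome 2, 25653120 to 25656217), a carrier of small lipophilic molecules, fell from 4514 ± 903 to 809 ± 106 FPKM (-2.47, limma adjusted p 5.1e-04). The lipid enzyme genes Pla2g5 (ENSMUSG00000041193, chromosome 4, 138799244 to 138863482), Lipf and Lipk fell from lower levels, by 2.79, 3.07 and 2.65. Ly6g5b fell by 2.22 to 102 ± 20.5 FPKM, Bricd5 by 2.67 and Bglap2 by 2.52.

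The largest rises included Crisp1 (ENSMUSG00000025431, chromosome 17, 40293758 to 40319207), a secreted protein of more distal segments, from 167 ± 159 to 1001 ± 93.1 FPKM (2.98, limma, Benjamini-Hochberg adjusted p 0.021). The growth factor binding protein Igfbp2 rose from 12.7 ± 1.77 to 86.0 ± 50.3 FPKM (0.024), the protease inhibitor Pzp by 2.32 (0.030), the defensin Defb6 by 2.28 (0.035) and the neuropeptide receptor Npy6r by 2.26 (0.0093). The metallothioneins Mt3 and Mt2 rose by 2.22 and 1.94, Wfdc16 by 1.84 and the RNA-binding Bicc1 by 1.60 (limma adjusted p 0.0062). Sumo2 (ENSMUSG00000020738, chromosome 11, 115523102 to 115536276) was listed at 0 in WT, with no event of any kind there, and its main first exon had 28.1, 46.5 and 33.4 FPKM in dKO (limma adjusted p 1.5e-04). Whether the missing events of WT come from the assembly of transcripts or from expression was not tested. The calls of Crisp1, Igfbp2, Pzp, Defb6, Mt3, Mt2, Wfdc16 and Bglap2 were each lost in 3 to 5 of the 9 fits that left out 1 library. Those libraries were WT replicates 2 and 3 and dKO replicates 1, 2 and 3, with a highest adjusted p of 0.0599 to 0.131 per gene.

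Among pathway genes, Amot rose by 0.67 to 110 ± 7.73 FPKM and Amotl2 by 1.07 to 12.8 ± 0.288 (limma, Benjamini-Hochberg adjusted p 0.019 and 0.027). Their products bind Yap. Wwc2, an upstream activator of the pathway, rose by 0.57, Wwtr1, which encodes the Yap paralog Taz, by 0.41, and the Yap target Ccn1 by 0.92. Of 23 tested Hippo genes 4 were called higher and 0 lower, against 10 and 0 adjusted over the list alone. The list was higher by camera (median 0.24, adjusted p 1.4e-04), but not with an estimated correlation (0.085). Of 18 YAP/TAZ target genes 2 were called higher and 0 lower, against 3 and 1 adjusted over the list alone, and the list was not called (camera adjusted p 0.12). It shares Lats2, Amotl2 and Ptpn14 with the Hippo list, and the called Amotl2 counts in both.

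Etv4 (ENSMUSG00000017724, chromosome 11, 101769742 to 101785371) fell from 27.8 ± 4.67 to 8.22 ± 1.15 FPKM (-1.64, limma, Benjamini-Hochberg adjusted p 8.5e-04). Etv5 (ENSMUSG00000013089, chromosome 16, 22381309 to 22439719) fell from 102 ± 1.21 to 47.9 ± 4.47 FPKM (-1.08, limma adjusted p 7.5e-04). The phosphatase genes Dusp6 and Dusp5, which ERK signalling induces, fell by 0.80 and 0.43 (0.015 and 0.042). Of 16 tested ERK response genes 4 were called lower and 0 higher, against 6 and 0 adjusted over the list alone, and the list was lower (median -0.20, camera adjusted p 6.0e-05, 0.086 with an estimated correlation). The calls of Amot, Amotl2, Wwc2, Wwtr1, Ccn1, Dusp6 and Dusp5 were lost in 3 to 9 of the 9 fits that left out 1 library, each of the 9 libraries among them. The highest adjusted p was 0.0592 for Dusp6 and up to 0.151 for Wwtr1.

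Rnase10 (ENSMUSG00000021872, chromosome 14, 51007751 to 51010758), which is needed for sperm binding in mice, fell from 2117 ± 270 to 763 ± 90.1 FPKM (-1.47, limma, Benjamini-Hochberg adjusted p 0.0018). Srd5a1, which makes dihydrotestosterone, fell by 1.01 (0.019). Of 15 initial segment genes 5 were called lower and 0 higher, against 7 and 1 adjusted over the list alone. The initial segment list was lower (median -0.54, camera adjusted p 3.3e-04, 0.086 with an estimated correlation). Crisp4 (ENSMUSG00000025774, chromosome 1, 18115191 to 18145902) fell by 2.06 to 9.44 ± 2.08 FPKM (limma adjusted p 5.7e-04). Lcn10 (ENSMUSG00000047356, chromosome 2, 25682726 to 25686081) fell by 1.68 to 295 ± 48.4 FPKM (7.9e-04). Both are on the list of caput and later segment genes, where 3 of 11 were called lower and 1 higher, against 5 and 1 adjusted over the list alone. That list was lower too (median -0.69, camera adjusted p 5.4e-04, 0.086 with an estimated correlation). The lipocalin family shares 2 of its genes with the initial segment list and 4 with the caput list, and was lower (median -1.65, 4.3e-04, 0.085 estimated). The call of Srd5a1 was lost without WT replicate 2 or 3 or dKO replicate 1 or 2, with an adjusted p up to 0.0852.

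Cell cycle genes were higher. Cenpf, Ccna2, Top2a and Birc5 rose by 0.94, 0.92, 0.88 and 0.75, and 28 of 29 tested members had a positive log2 fold change. Of these 5 were called higher and 0 lower, against 13 and 0 adjusted over the list alone (median 0.58, camera adjusted p 1.1e-08, 0.36 with an estimated correlation). Among cell type markers, Car2 of narrow and clear cells fell by 1.66 to 7.61 ± 0.953 FPKM (limma, Benjamini-Hochberg adjusted p 9.2e-04). Of 7 narrow and clear cell markers 1 was called lower, against 3 adjusted over the list alone (median -0.48, camera adjusted p 0.0077, 0.086 estimated). The endothelial list, with Tie1 lower by 0.63, was lower (median -0.37, camera adjusted p 0.0016, 0.36 estimated), with 1 of 10 genes called, against 2 adjusted over the list alone. The cystatin list was lower (median -0.08, adjusted p 0.033, 0.36 estimated), with 2 of 5 genes called lower over all genes and over the list alone. The basal cell list was lower (median -0.32, 0.033, 0.37 estimated), with 0 of 11 genes called by limma either way. Actg2 of smooth muscle fell by 1.77, Pdgfra of fibroblasts by 0.55, the Wnt effector Lef1 by 1.46 and Defb30 by 1.04, and Tcf7 rose by 0.77. The calls of Cenpf, Ccna2, Top2a, Birc5, Tie1, Actg2, Pdgfra, Defb30 and Tcf7 were lost in 3 to 7 of the 9 fits that left out 1 library, among them every WT and dKO replicate and tKO replicates 1 and 3, with an adjusted p up to 0.136. The basal cell list was not called without WT replicate 3 (0.0791) or dKO replicate 2 (0.065), nor the cystatin list without WT replicate 1 (0.133) or dKO replicate 1 (0.0733).

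Altogether 10 of 25 lists were called in dKO versus WT, 2 higher and 8 lower. None was called with an estimated correlation, where the smallest adjusted p was 0.085 and 6 lists had an unadjusted p under 0.05, and 10 were called with fry. The lists of principal cell markers, tight junction genes, macrophage and dendritic cell markers, fibroblast and matrix genes, smooth muscle markers, ciliated efferent duct markers, Notch, Wnt, TGF-beta and p53 genes, dissection stress genes, beta-defensins, claudins and ribosomal proteins were not called. For the Notch, claudin, smooth muscle and ribosomal lists the median was above 0 and the test pointed down, and for principal cell markers the mean was below 0 and the test pointed up.

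**Figure D2:**
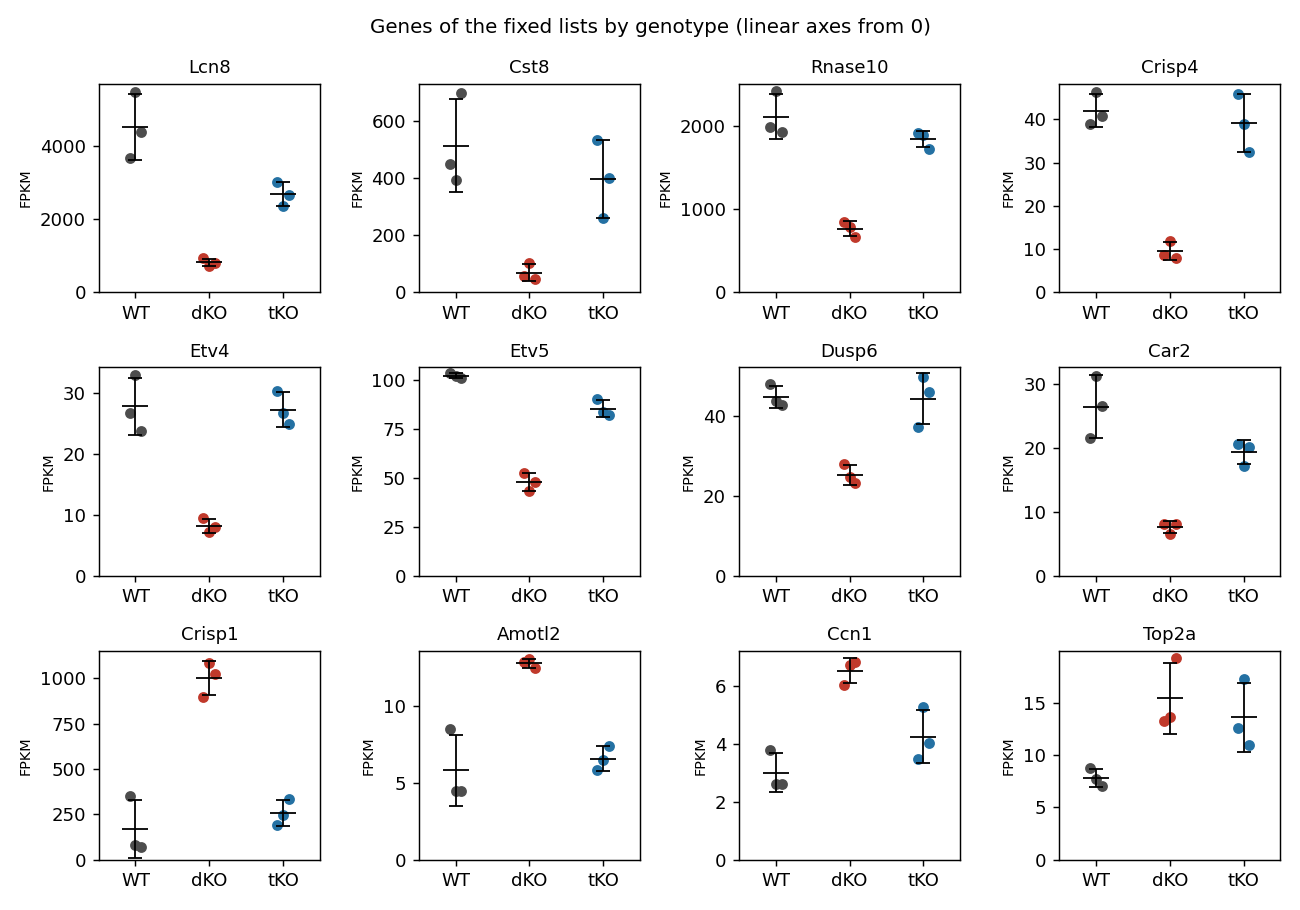
FPKM of 12 genes named in the text in the 9 libraries (points) with the mean and SD of each group, on linear axes from 0. Lcn8, Cst8, Rnase10, Crisp4, Etv4, Etv5, Dusp6 and Car2 have all dKO libraries below all WT and all tKO libraries.

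The comparison of tKO with WT asks what remains changed when Yap is lost along with both kinases. Few genes differed. Apobec3 and a form of Cep85 rose in tKO, Pla2g5 and Cst12 fell as they did in dKO, and Lcn8, Rnase10, Etv4 and Etv5 were not called. Of 12021 genes 19 were called changed, 9 higher and 10 lower, 12 of them by at least 1 on the log2 scale, 6 up and 6 down, and 1585 had an unadjusted p under 0.05. The libraries of the groups were separated in all 19, and in 18.8% of tested genes. The count was 153 without tKO replicate 1 and 5 without WT replicate 2. It was 11 and 9 without WT replicates 1 and 3, 10 and 12 without dKO replicates 1 and 3, and 8 without tKO replicate 2.

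Cep85 (ENSMUSG00000037443, chromosome 4, 134129858 to 134187112), which encodes a centrosomal protein, was counted by a last exon at 134164112 to 134164757. This exon had 160, 254 and 110 FPKM in the tKO libraries and was listed at 0 in WT and dKO (limma, Benjamini-Hochberg adjusted p 4.5e-06). The form of Cep85 that skips the exon had 2.30 to 2.79 FPKM in WT, 2.47 to 3.29 in dKO and 3.03 to 3.85 in tKO. The main first exon of Cep85, at 134186943 to 134187112, had the same values as that form in WT and dKO, and 163, 11.9 and 114 FPKM in the tKO libraries. Apobec3 (ENSMUSG00000009585, chromosome 15, 79891659 to 79915906), a cytidine deaminase that restricts retroviruses, rose from 1.21 ± 0.615 to 18.3 ± 5.25 FPKM (3.14, limma adjusted p 0.0077). The form of Apobec3 that skips the exon at 79899020 to 79899118 had 14.2, 15.3 and 23.3 FPKM in tKO and was listed at 0 in WT and dKO. Sumo2 was listed at 0 in WT and had 36.8 ± 12.7 FPKM in tKO (limma adjusted p 7.8e-05), with the same doubt about assembly.

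Fxyd2, which encodes a regulator of the sodium pump, rose by 1.57 (limma, Benjamini-Hochberg adjusted p 0.017), the ribosomal protein gene Rplp0 by 0.74, and the paralogs Tmem254b and Tmem254c, whose reads could not be separated, by 0.90 each. Pla2g5 fell from 41.7 ± 7.4 to 9.07 ± 2.87 FPKM (-2.12, limma adjusted p 0.012) and Cst12 from 123 ± 12.8 to 37.7 ± 15.9 FPKM (-1.75, limma adjusted p 0.0495). The semaphorin Sema3b fell by 1.30, the lipase Lipc by 1.08, the kinase Pdk1 by 0.90, the dipeptidase Pepd by 0.79 and the asparagine synthetase Asns by 0.73. Sumo2, Apobec3 and Yap1 were called in each of the 9 fits that left out 1 library, and Cep85 in the 6 in which it passed the filter, those that kept all tKO libraries. The others lost the call in 1 to 8 of the 9 fits, Pla2g5 only without WT replicate 2 (adjusted p 0.0667) and Lipc only without a WT replicate (up to 0.083). For the rest, each of the 9 libraries but tKO replicate 1 ended at least 1 call, with an adjusted p up to 0.157.

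Lcn8 had 2685 ± 327 FPKM in tKO against 4514 ± 903 in WT and was not called (-0.74, limma, Benjamini-Hochberg adjusted p 0.18), nor were Lcn10 (-0.55, 0.18), Cst8 (-0.39, 0.69), Rnase10 (-0.19, 0.63), Crisp4 (-0.11, 0.82) and Lypd8 (-2.09, 0.090). Without tKO replicate 1, Lypd8 was called (-2.51, limma adjusted p 0.022). Etv5 (-0.26, 0.30), Etv4 (-0.02, 0.98), Dusp6 (-0.02, 0.96), Car2 (-0.42, 0.31) and Crisp1 (0.99, 0.46) were not called either. By camera, 3 lists of segment genes were lower. For initial segment genes, 0 of 15 were called over all genes or over the list alone (median -0.19, adjusted p 0.015, 0.39 with an estimated correlation). For caput and later segment genes, 1 of 11 was called lower, against 3 adjusted over the list alone (median -0.55, adjusted p 0.0011, 0.24 estimated). For lipocalins, 0 of 7 were called, against 3 lower adjusted over the list alone (median -0.55, 0.0011, 0.22 estimated). The initial segment list was not called without WT replicate 2 (0.085) or tKO replicate 2 (0.166).

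The cell cycle list was higher (median 0.45, camera adjusted p 3.3e-05, 0.55 with an estimated correlation), with 0 of 29 genes called by limma, against 7 higher adjusted over the list alone. Ciliated efferent duct markers were higher (median 0.92, 2.6e-04, 0.44 estimated), with all 9 tested members positive, 0 called and 5 higher adjusted over the list alone. Their FPKM summed to 48.2, 146 and 90.6 in tKO replicates 1, 2 and 3, against 38.5 to 42.9 in WT and 35.0 to 51.8 in dKO, so replicate 2 stands apart and replicate 1 lies within dKO. Among them Foxj1, the transcription factor of motile cilia, had 26.7 ± 10.4 FPKM in tKO against 12.8 ± 0.639 in WT (0.93, limma, Benjamini-Hochberg adjusted p 0.25), Ccdc39 differed by 1.26 (0.18) and Tekt1 by 1.22 (0.26). Basal cell markers were lower (median -0.55, camera adjusted p 0.0011, 0.39 estimated), with 0 of 11 called and 4 lower adjusted over the list alone. The members did not all move together, with 9 negative and 2 positive. Krt5 had 25.4 ± 11.2 FPKM in tKO against 52.8 ± 6.93 in WT (-1.10, limma adjusted p 0.14) and Krt15 4.80 ± 1.68 against 22.7 ± 9.92 (-1.97, 0.090). Without tKO replicate 1 limma called Krt5 (-1.42, adjusted p 0.016), Foxj1 (1.28, 0.038) and Ccdc39 (1.64, 0.029). Altogether 6 of 25 lists were called, 2 higher and 4 lower, 0 with an estimated correlation (smallest adjusted p 0.22, 2 unadjusted) and 1 with fry.

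The comparison of tKO with dKO adds the loss of Yap to that of both kinases, but the shares of skipped transcripts were not equal. In every tKO library a smaller share lacked the exons of Stk4 and Stk3 than in every dKO library (means 47.1% against 64.3% and 39.9% against 56.4%). The form that keeps the exons was higher in all tKO libraries for Stk4 (exact permutation p 0.1) but not for Stk3 (0.4), where dKO replicate 3 was above every tKO library, at 4.28 FPKM. Whether deletion itself was weaker is thus not settled, and differences cannot be assigned to Yap alone. Genes that had fallen in dKO were higher in tKO, among them Cst8, Crisp4, Lcn8, Rnase10, Etv4 and Car2. Folh1, Ly6e, Clu and Wfdc16 were lower. Of 12021 genes 248 were called changed, 145 higher and 103 lower, 112 of them by at least 1 on the log2 scale, 69 up and 43 down, and 2011 had an unadjusted p under 0.05. All 248 separated the libraries, as did 22.1% of tested genes. The count was 124, 91 and 96 without dKO replicates 1, 2 and 3, and 104 without tKO replicate 2 and 146 without tKO replicate 3. The balance moved too, to 77 higher and 19 lower without dKO replicate 3 and 118 and 110 without WT replicate 1.

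Cst8 rose from 68.3 ± 30.8 to 396 ± 137 FPKM (2.55, limma, Benjamini-Hochberg adjusted p 0.012), Crisp4 from 9.44 ± 2.08 to 39.1 ± 6.71 (1.95, 0.0017) and Lcn8 from 809 ± 106 to 2685 ± 327 (1.73, 0.0050). Rnase10 rose from 763 ± 90.1 to 1847 ± 101 FPKM (1.28, limma adjusted p 0.0059) and Lcn10 from 295 ± 48.4 to 639 ± 25.7 (1.12, 0.0087). The sialyltransferase St3gal2 rose from 19.6 ± 2.40 to 70.1 ± 3.07 FPKM (1.79, limma adjusted p 6.4e-04). Apobec3 rose by 2.75, the cytidine deaminase Cda by 1.68, AU015791 by 2.14, the matrix protein Tecta by 1.95 and Hivep3 by 1.67, and the last exon of Cep85 was listed at 0 in dKO. Folh1, which encodes a folate hydrolase, fell from 57.6 ± 1.10 to 15.3 ± 3.33 FPKM (-1.87, limma adjusted p 0.0019) and Ly6e from 608 ± 56.0 to 224 ± 62.4 (-1.47, 0.010). Pik3c2g fell by 2.19, Pdzk1ip1 by 1.81, Cpne5 by 2.49, the retinol transporter Stra6 by 2.33, Wfdc16 by 1.78 and Wfdc6b by 1.65, and Nxpe2 fell to 1.27 ± 0.755 FPKM. The calls of AU015791, Tecta, Hivep3, Cpne5, Stra6, Nxpe2, Wfdc16 and Wfdc6b were lost in 2 to 7 of the 9 fits that left out 1 library. Every library but WT replicate 1 ended at least 1 of these calls, with an adjusted p up to 0.127.

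Etv4 rose from 8.22 ± 1.15 to 27.3 ± 2.85 FPKM (1.62, limma, Benjamini-Hochberg adjusted p 0.0019) and Etv5 from 47.9 ± 4.47 to 85.4 ± 4.41 (0.82, 0.0051). Dusp6 rose by 0.78 and Spred1, a feedback inhibitor of the same pathway, by 0.61. Of 16 ERK response genes 5 were called higher and 0 lower, against 9 and 1 adjusted over the list alone (median 0.36, camera adjusted p 3.2e-06, 0.14 with an estimated correlation). Hippo genes were lower as a list (median -0.16, camera adjusted p 4.0e-04, 0.14 estimated), with Yap1 the 1 gene of 23 called lower, against 4 adjusted over the list alone. The list holds the deleted gene itself. Without Yap1 the list of the other 22 genes was still lower (median -0.15, camera adjusted p 0.0040, 0.29 estimated), with 0 called. That test was added after the data had been seen. Of the 23 genes, 7 had a positive log2 fold change. Amot (-0.52, limma adjusted p 0.063), Amotl2 (-0.87, 0.071) and Wwc2 (-0.55, 0.059) were not called, and each was called without WT replicate 1 (0.044, 0.012 and 0.038). The call of Dusp6 was lost without dKO replicate 2 or 3 or tKO replicate 2 or 3, and that of Spred1 without dKO replicate 2 or 3 or tKO replicate 2, with an adjusted p up to 0.0693.

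Car2 rose by 1.24 to 19.3 ± 1.91 FPKM (limma, Benjamini-Hochberg adjusted p 0.0065), Actg2 by 1.57, Tie1 by 0.65, Lef1 by 1.09, Defb30 by 1.02 and Rps13 by 0.97, and Clu fell by 1.44 to 1289 ± 492 FPKM. The endothelial list was higher (median 0.45, camera adjusted p 7.2e-05, 0.31 with an estimated correlation), with all 10 genes positive, 1 called higher and 4 adjusted over the list alone. Ciliated efferent duct markers were higher (median 0.89, 0.0014, 0.42 estimated), with 0 of 9 called by limma and 7 adjusted over the list alone, but their FPKM sum in tKO replicate 1 (48.2) lay within dKO (35.0 to 51.8) and replicate 2 stood apart (146). The FPKM sums of germ cell markers were 13.8, 72.6 and 20.6 in tKO against 4.44 to 10.4 in dKO, also highest in replicate 2, where Ldhc gave 36.9. With 3 of 16 members tested and 0 called, that list was too short for camera. Initial segment genes were higher (median 0.20, camera adjusted p 0.048, 0.38 estimated), with 4 of 15 called higher and 0 lower, against 6 and 1 adjusted over the list alone. Cell cycle genes (median -0.17, camera adjusted p 0.036, 0.74 estimated) and tight junction genes (median -0.21, 0.041, 0.29 estimated) were lower. None of the 29 cell cycle and 13 tight junction genes was called by limma, against 1 lower and 1 higher adjusted over the list alone. Altogether 7 of 25 lists were called, 4 higher and 3 lower, 0 with an estimated correlation (smallest adjusted p 0.14, 3 unadjusted) and 8 with fry.

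Of these calls, Actg2, Tie1, Lef1, Defb30, Rps13 and Clu were lost in 3 to 9 of the 9 fits that left out 1 library, each of the 9 libraries among them, with a limma adjusted p up to 0.122. The initial segment list was not called by camera without dKO replicate 1 (0.282) or 3 (0.0873) or tKO replicate 1 (0.152) or 3 (0.071). The cell cycle list was not called without dKO replicate 3 (0.324) or tKO replicate 1 (0.0982) or 3 (0.376), nor the tight junction list without dKO replicate 1 (0.0668) or 2 (0.0569) or tKO replicate 2 (0.203).

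**Figure D3:**
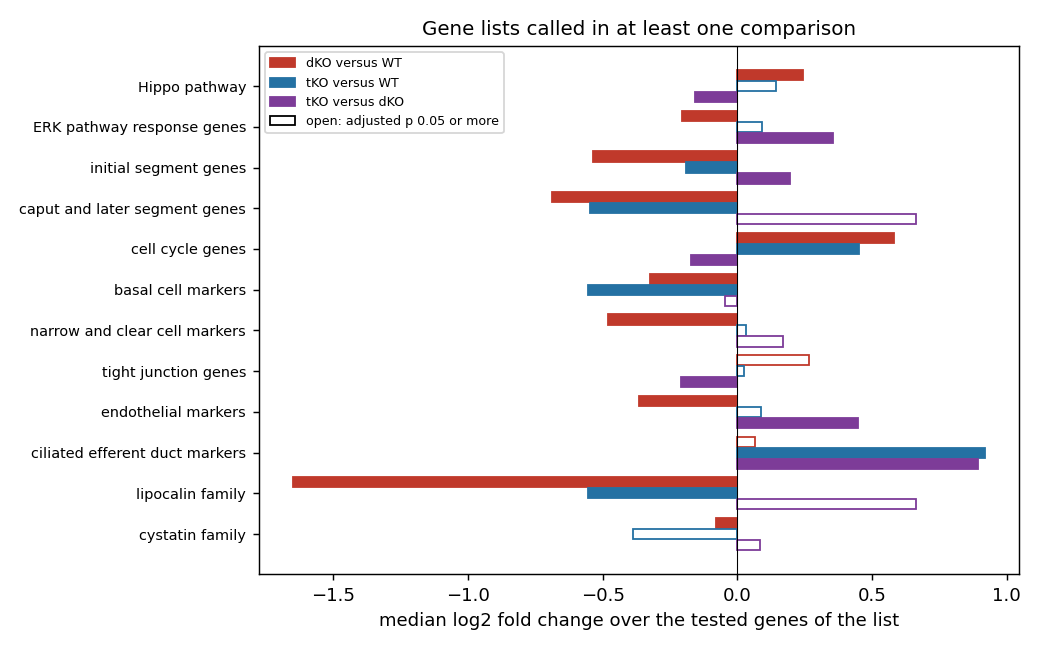
Median log2 fold change over the tested genes of each of 12 lists called in at least 1 comparison, with filled bars for a camera adjusted p under 0.05 at a preset correlation of 0.01 and open bars for lists not called. ERK response genes are at -0.20 in dKO versus WT and at 0.36 in tKO versus dKO.

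The changes of dKO were followed into tKO, where Yap was lost as well and the skipped shares of Stk4 and Stk3 were smaller than in dKO. Of the 457 genes changed in dKO versus WT, 151 (33.0%) were called in the opposite direction in tKO versus dKO, 45 of the rises and 106 of the falls. Independent lists of the same sizes would share 1.51 and 3.39. These comparisons share the dKO libraries. Simulated groups with tKO equal to dKO gave 0 to 2 such genes in 100 draws, and with tKO equal to WT 308 to 361. Those draws called 351 to 408 and 352 to 403 genes in dKO versus WT, fewer than 457, so their counts have a smaller base. The 151 genes include Lcn8, Cst8, Rnase10, Crisp4, Lcn10, Etv4, Etv5, Dusp6, Car2 and Lef1 among the falls and Wfdc16 among the rises. The change against WT was smaller in tKO than in dKO for 448 of the 457 genes, with a median ratio of 0.31, and had the same sign for 386 (84.5%). Choosing genes by their change in dKO favours a smaller one in tKO, and the shared WT libraries favour the same sign. In 100 draws with tKO equal to dKO, 50.5% to 64.0% of the genes called were smaller, at a median ratio of 0.97 on average, and 98.7% to 100% had the same sign. With tKO equal to WT these values were 98.9% to 100%, 0.02 and 50.7% to 61.3%. The median log2 fold change of the dKO rises was 0.83 in dKO and 0.26 in tKO, and that of the falls -0.96 and -0.29.

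In tKO versus WT, 9 of the 457 were called in the same direction: Sumo2, Fxyd2 and Ppih higher, and Cst12, Pla2g5, Sema3b, Pepd, Tenm4 and Gm44930 lower. For Sumo2 the same doubt about assembly in WT applies. All are given because they are few. Ppih rose by 1.40 in dKO and 1.31 in tKO, and Tenm4 fell by 1.58 and 1.37. Independent lists would share 0.13 rises and 0.23 falls, and both comparisons share the WT libraries, which raises such counts. Draws with tKO equal to dKO gave 293 to 351 kept genes, where 351 to 408 were called in dKO versus WT, and with tKO equal to WT 0 to 1. Across genes, the log2 fold changes of dKO and tKO against WT had a Pearson's r of 0.44 and a covariance of 0.0726. Simulated groups without any difference from WT gave an r of 0.46 to 0.54 and a mean covariance of 0.0315, since the 3 WT libraries are shared. With tKO equal to dKO these were 0.71 to 0.76 and 0.0861, and with tKO equal to WT 0.32 to 0.41 and 0.0316. The count of opposite calls was 61 and 69 without WT replicates 2 and 3, 75, 54 and 54 without dKO replicates 1, 2 and 3, and 74 and 94 without tKO replicates 2 and 3. The count of kept calls was 34 without tKO replicate 1, 1 and 3 without WT replicates 2 and 3, 3 without dKO replicate 1 and 4 without tKO replicate 2.

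**Figure D4:**
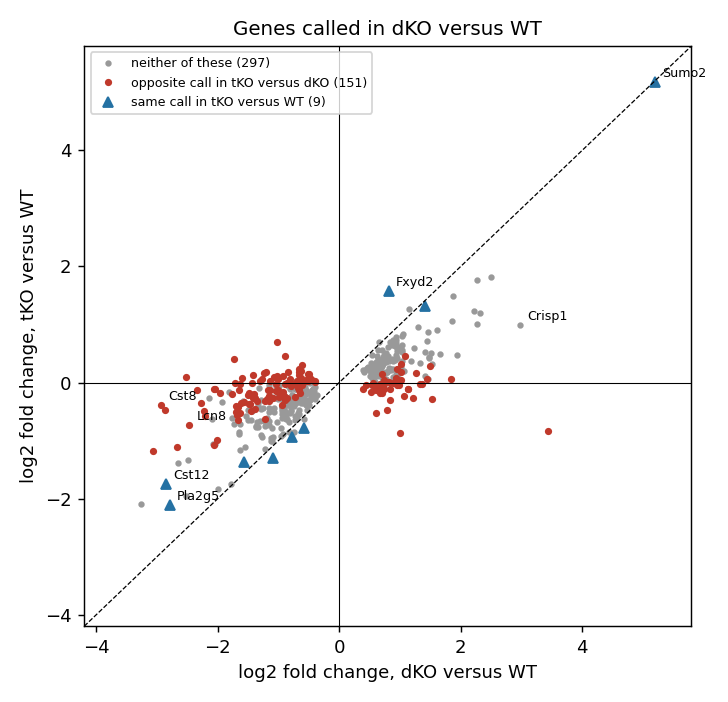
Log2 fold change in tKO versus WT against that in dKO versus WT for the 457 genes changed in dKO, coloured by whether the gene was called in the opposite direction in tKO versus dKO (151) or in the same direction in tKO versus WT (9). The dashed line marks equal change, and for Sumo2, listed at 0 in WT, the position depends on the pseudocount.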

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

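The inclusion of exons and introns lies outside the gene values and was tested only after the event values had been seen. A pair of events gives the share of transcripts that keep an exon or intron, and 9576 pairs in 5039 genes were tested with limma on percentages. Benjamini-Hochberg adjusted p-values under 0.05 were found for 7 pairs in dKO versus WT, 7 in tKO versus WT and 8 in tKO versus dKO, against 374, 409 and 415 at an unadjusted p under 0.05. Of the targeted exon pairs, that of Stk3 was called in dKO versus WT only and that of Stk4 in no comparison, so large differences can be missed. The calls given here are of exons outside Stk3 and Stk4 and differed from WT by at least 10 percentage points. Shares fixed at 0% or 100% in a whole group have no spread, so the test overstates how sure they are. Unlisted events were taken as 0, so a form missing from the assembly of a group also gives 0% or 100%. Such gaps could not be told apart from splicing. No explanation was tested for any of them.

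The largest of these differences was in Camk2d, which encodes a calcium-dependent kinase. Its exon on chromosome 3 at 126841485 to 126841573 was kept in 94.3% of transcripts in WT and 31.2% in tKO, a difference of -63.1 points (limma adjusted p 0.011). The tKO libraries had 23.4%, 32.9% and 37.4%, and the dKO libraries 97.9%, 98.7% and 99.4%. Also in tKO versus WT, inclusion differed by 17.9 points in Raph1, -16.6 in Macrod1 and 17.3 in Anxa4, and all WT and dKO libraries were at 0% for Raph1 and Anxa4 and at 100% for Macrod1. In dKO versus WT, Mink1, a kinase gene, differed by 16.6 points, from 78.5% to 95.1%, and the replication gene Orc6 by -19.7 points, from 100% to 80.3%. Abat differed by -10.2 points, and both Orc6 and Abat were at 100% in every tKO library. Camsap1 differed by 12.9 points and Capg by -10.7 points, each by the same amount in dKO and in tKO, since both knockout groups stood at 100% for Camsap1 and at 0% for Capg.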

How the results depend on the processing

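Median-of-ratios scaling, first exons only, last exons only, the larger sum in each library and lists without Yap1 were added after the data had been seen, as were a pseudocount of 0.1 and only the 6 libraries for the targeted genes, and all other alternatives were planned. Tests that need read counts (DESeq2) were also planned and could not be run on FPKM.

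Genes changed in dKO versus WT numbered 335 to 467 under quantile normalization, a pseudocount of 0.1, no filter, median-of-ratios scaling, the other gene values and a fit of only the 6 libraries, against 457. With an absolute log2 fold change of at least 1 they numbered 185, 12 and 112 in dKO versus WT, tKO versus WT and tKO versus dKO, a subset by construction. Quantile normalization gave 33 genes in tKO versus WT and no filter 29, and only the 6 libraries gave 8, and 158 in tKO versus dKO; the cause was not tested. The genes of dKO kept in tKO numbered 5 with last exons only, against 9, and the cause was not tested. With the replicate number as a block the counts were 234, 3 and 141, with 79 opposite and 1 kept, though the same-numbered libraries were not alike; a block also takes residual degrees of freedom. A library left out leaves fewer samples. It gave 106 to 451 genes in dKO versus WT, 5 to 153 in tKO versus WT and 91 to 331 in tKO versus dKO, 54 to 146 opposite and 1 to 34 kept, and an r of 0.39 to 0.52. Without tKO replicate 1 there were 153 genes in tKO versus WT and 331 in tKO versus dKO, 18 and 182 of them in the full result.

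Taking Yap1 out of the lists left the 10, 6 and 7 calls. Lists called numbered 9 to 10, 5 to 7 and 5 to 9 with a library left out, and 0, 0 and 0 with an estimated correlation, which leaves 0 of 23 calls. Fry gave 1 list in tKO versus WT and left 14 of 23 calls, and the block left 21. The totals of Stk4 and Stk3 were called under no alternative, and Yap1 was called lower in tKO under each one that tested it, which last exons only did not. The sign of the uncalled Stk4 difference in tKO versus dKO and Stk3 difference in dKO versus WT was not stable, at -0.05 to 0.12 and -0.15 to 0.01 with a library left out, and the first was -0.07 with last exons only. Of 109 gene results named, 90 were called, and 33 of these kept call and direction under every alternative that tested them. Over 1938 alternative values 357 lost the call, 9 gained it and 0 reversed. Amot in tKO versus dKO gained it with median-of-ratios scaling and Amotl2 with only the 6 libraries. A change of sign was not counted as reversed where neither value was called. With a library left out, uncalled Etv4, Dusp6 and Crisp4 in tKO versus WT ranged over -0.12 to 0.11, -0.11 to 0.09 and -0.23 to 0.01. No scaling moved the median log2 fold change of all genes by more than 0.1. Limits include 3 libraries per group, unknown depth and unlisted zeros.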

Other observations

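The tests of caput tissue and of the epithelial share in dKO, of tKO replicate 2 as the source of the ciliated markers, and of the first exon of Cep85 were chosen only after the results were seen. The splits of the libraries, the efferent duct test and the neighbour test were written down before their results were known.

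Other splits of the 6 libraries of a comparison into groups of 3 were fitted in the same way. In each of the 3 comparisons 1 of the 10 splits, the real one, gave as many genes. The real values were 457, 19 and 248 genes and the highest other splits gave 2, 1 and 2. Every other split mixes both genotypes in each group, so any real difference adds to the spread and lowers its count. These low counts are therefore no measure of what chance gives. With 10 splits no share under 0.05 can be reached.

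Initial segment genes were lower in dKO as a list, with 5 of 15 called and no list call at an estimated correlation (camera adjusted p 0.086). A dissection with more caput tissue may contribute. The list of caput and later segment genes had a median log2 fold change of -0.69 (95% bootstrap range -2.06 to 0.08), and this range does not exclude it. The members of that list were split, with 8 of 11 negative and 3 positive. The 1 called higher was Crisp1 of more distal segments (2.98), and 3 were called lower, so the list cannot decide. A lower share of epithelial cells would raise the markers of other cell types alike. The endothelial list had a median of -0.37 (-0.56 to -0.14), while fibroblast, smooth muscle and macrophage lists had -0.00, 0.02 and 0.09, so no joint rise was seen. The rule for this test was set when the endothelial list was already known to be lower, and its range resamples genes. It therefore cannot exclude a lower epithelial share. Loss of Mst1 and Mst2 in the cells themselves stays open as the biological explanation, beside more caput tissue and a lower epithelial share.

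Ciliated efferent duct markers were higher in tKO as a list, with 0 of 9 called and no list call at an estimated correlation (camera adjusted p 0.44). Their FPKM summed to 38.5, 42.9 and 41.9 in WT, 43.9, 35.0 and 51.8 in dKO and 48.2, 146 and 90.6 in tKO. Of 11 markers 10 had a value, and WT libraries held them too; the most abundant were Rsph1, at 15.1, 56.9 and 25.7 FPKM in the tKO libraries, and Foxj1, at 15.2, 35.4 and 29.4. Without tKO replicate 2 the list median was still 0.64 (0.42 to 0.77). That range resamples the genes of the list and does not measure the spread between libraries. By the sums, replicate 3 lay above every WT and dKO library and replicate 1 lay within dKO. Replicate 2 was thus not the only high library, but the rest may come largely from replicate 3. Efferent duct tissue, which lies next to the initial segment, could bring such transcripts. The test took Lrp2, Cubn, Amn and Dab2, expressed by the non-ciliated cells of that duct. Only Lrp2 and Dab2 had enough FPKM to be tested; their median of 0.55 was above that of 98.1% of 10000 random lists, and so met the test as first written. Aqp1, Slc9a3, Aqp9 and Esr1, which both ducts can express, were looked at afterwards. They pointed the same way, at 0.76, 0.98, 0.86 and 0.45, and none was called (limma, Benjamini-Hochberg adjusted p 0.18 to 0.28). Germ cell markers, which were not part of the test, moved with the ciliated ones, at 13.8, 72.6 and 20.6 FPKM in tKO, 7.30 to 10.6 in WT and 4.44 to 10.4 in dKO. Since 2 of 4 genes are too small a part, the explanation was then left open, as was a change of the tKO tissue itself.

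Some genes differed in tKO from the mean of the other groups. A chromosome segment whose strain differs between the tKO mice and the others may explain part of them. Of 126 genes at an unadjusted p under 0.001, 37 had another within 1000000 bases, where 10000 random placements gave a median of 23 and 33 at their 95th percentile, so the test as first written was met. With 1 gene per symbol family, a repeat added after that result, 31 of 123 had a neighbour, against 32 at the 95th percentile. The 126 include genes that differ from 1 group only, such as Sumo2 and Etv4. A set of 102 differed from WT and from dKO in 1 direction at an unadjusted p under 0.05, a choice also made after that result. Of these 32 had a neighbour, against 24 at the 95th percentile, and with 1 gene per symbol family 26 of 99, against 23. These counts fit a segment from another strain, but do not show one, since neighbours can also share regulation. In dKO versus WT 137 of 344 genes at an unadjusted p under 0.001 had a neighbour, equal to the random median of 137. Apobec3 and Cep85 had no such neighbour, and Yap1 had Cfap300. Chromosome 4 from Cep85 onward held 10 of the 126, the most in any run of 217 tested genes, where random placements gave 9 at the 95th percentile. The length of the run was set by Cep85 after the values were seen. The level and splicing of Apobec3 are known to vary between inbred mouse strains. For Cep85, the main first exon was higher in tKO by 4.08 on the log2 scale, but in tKO replicates 1 and 3 it is the sum of the last exon and the form that skips it. It therefore cannot tell a change of that exon from one of the gene. The form that skips the exon differed by 0.26. Loss of Yap remains open as the biological explanation, beside a strain segment. Efferent duct tissue in the tKO samples also stays open, as do, against dKO, the smaller skipped shares of Stk4 and Stk3 in tKO.

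Besides germ cell and ciliated markers, tKO replicate 2 had the highest sums of adipocyte markers at 39.3, macrophage and dendritic cell markers at 412 and fibroblast and matrix genes at 2051. In 30 genes, 33 single values were at 0 while both other libraries of the group had at least 5 FPKM. Values just above 0 are not in this count. Col1a2, for example, had 0.036 and 0.038 FPKM in WT replicates 1 and 2 and 128 in WT replicate 3.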
